A study of Glycine max with 4 samples.

How the data were processed

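Small RNA was sequenced from roots, stems and leaves of soybean plants 14 days after germination and from cotyledons of seeds 20 days after flowering, with 1 library per organ. Per the labels' protocols, RNA of about 17 to 27 nt was cut from a polyacrylamide gel, ligated to adapters at both ends, reverse transcribed and amplified by PCR before sequencing. The labels name an experimental station and growth chambers, and give growth chambers for roots, stems and leaves, so organ, stage and perhaps place of growth differ together.

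Each deposited file lists distinct sequences with a read count in the name of every entry, per the file headers, and holds no position and no gene name. These are whole numbers of reads, not scaled to the library. BWA is named in the submitters' processing notes, with no version and no stated role. How adapters were trimmed, which lengths were kept and which genome build was used are not given in the sources used here. All 4 libraries held lengths from 18 to 36 nt and sequences seen once, which were 86.2% of distinct sequences in root, 78.4% in stem, 80.6% in leaf and 81.4% in cotyledon. Since no genome was used here, results planned for genome windows, for regions around genes and for reads over gene lists were not analysed here, and abundant sequences were not assigned to loci. A RefSeq gene table was at hand but shares no identifier with the reads, so no value printed rests on it.

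Library totals were the sums of read counts, 8044543 in root, 9720527 in stem, 8059891 in leaf and 13364959 in cotyledon, and values were scaled to RPM, reads per 1000000 of these totals. Shares have 95% Wilson intervals. Ratios of RPM between 2 libraries have 95% exact intervals from the conditional binomial distribution of the reads. PCR copies without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. A count of 0 was given the limit of 3 reads, or 0.373 RPM in root, 0.309 in stem, 0.372 in leaf and 0.224 in cotyledon, and a ratio against it is a lower bound. With 1 library per organ no test and no p-value was possible.

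Families of miRNA were counted by exact match to 43 mature sequences of 35 families, grouped into 6 lists written from textbook knowledge before the data were examined. A family was called different at 4-fold or more in RPM with at least 100 reads in the higher library. The text names families past 4-fold against all 3 other organs, the 3 most abundant families of each library, and 2 to 4 per list. Of other sequences it names the 5 with the highest ratio of cotyledon to the highest other organ and the 5 with the lowest ratio to the lowest other organ, among those with at least 1000 reads in the higher library. miR167, miR1510, miR1511 and miR3522 are named also as the families above all 3 organs under every scaling, a choice made after their values were seen. For each list the median log2 ratio of cotyledon to the mean of the other organs was placed among 10000 random lists of the same size, each member drawn from the 50 nearest in mean level among 7775 other sequences of 20 to 22 nt. This describes these libraries and is no test. Exact matching misses reads of a family whose main form differs from the listed one, and miR1511 had 160 RPM in cotyledon as listed and 5165 RPM with length variants. Base changes are given from the listed miRNA to the read, with positions counted from 1 at the miRNA's 5' end.

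The sizes of call and the alternatives were fixed before the data were examined, except those named here. Added after the data were seen were a list of pieces of 18S, 5.8S and plastid rRNA and of plastid and cytosolic tRNA, the 24 nt reads above the mean of 23 and 25 nt, sequences with 1 base change, and median-of-ratios factors over other 20 to 22 nt sequences. Not fixed in advance either were the first-base shares over reads and over distinct sequences, the counts of distinct sequences at each length, the sequences shared between libraries and the counts of all sequences past 4-fold. TMM factors (trimming 30% of ratios and 5% of levels) and median-of-ratios factors over the listed families were written in Python. Thinning drew reads at random without replacement to the depth of root. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

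The call was tested on simulated data for cotyledon against leaf, with reads drawn for 2334 sequences well covered in cotyledon. Their cotyledon levels were used for both libraries, and changes were increases in cotyledon only. Decreases that leave few cotyledon reads were not simulated. Of 100 sequences changed 8-fold all 100 were called, of 100 changed 2-fold 0 were called, and of 2134 unchanged ones 0 were called. The intervals held the true ratio for 95.9% of sequences, which follows from drawing reads under the model that the intervals assume. The simulation holds no variation between plants.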

Results

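Small RNAs were sequenced from 4 organs of soybean (Glycine max): roots, stems and leaves of plants grown for 14 days, and cotyledons taken from developing seeds 20 days after flowering. Cotyledons are the storage leaves of the embryo. Each organ gave 1 library, so no difference below has a replicate check, and every interval covers counting error only. The files held 8044543 reads for root, 9720527 for stem, 8059891 for leaf and 13364959 for cotyledon. These reads fell into 1843110, 1767523, 1554545 and 4030594 distinct sequences in the same order, all between 18 and 36 nt long. The comparison of cotyledon with the other organs asks how the small RNAs of a developing seed differ from those of vegetative organs. Organ and stage differ together in it and cannot be told apart, and the labels leave open whether the place of growth differed too.

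The 24 nt class, the size of plant small interfering RNAs that guide DNA methylation, held a larger part of the reads in cotyledon than in any other organ. It made up 20.2% of cotyledon reads (95% Wilson interval 20.19 to 20.24). The share was 14.1% in root (14.07 to 14.12), 13.1% in stem (13.04 to 13.08) and 14.2% in leaf (14.13 to 14.18). The cotyledon share was 1.43 times that of root, 1.55 times that of stem and 1.43 times that of leaf. In every library the most frequent length was 21 nt, the size of most plant miRNAs, with 20.4% of reads in root, 24.8% in stem, 20.9% in leaf and 21.02% in cotyledon. The ratio of 24 nt to 21 nt reads was 0.962 in cotyledon, 0.690 in root, 0.526 in stem and 0.679 in leaf.

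**Figure D1:**
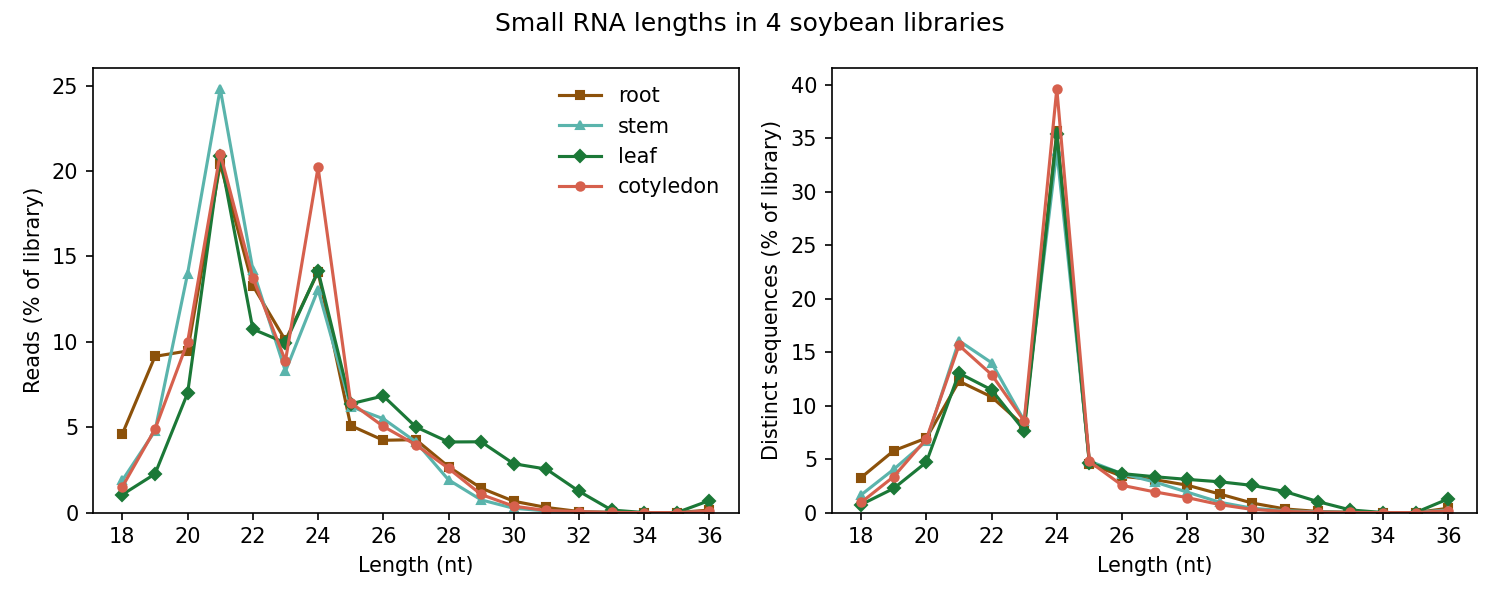
Percent of reads (left) and percent of distinct sequences (right) at each length in nt, with 1 line per library. The cotyledon line stands above the others at 24 nt in both panels, at 20.2% of reads and 39.7% of distinct sequences.

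Cotyledon 24 nt reads were spread over many sequences. Of the distinct sequences, 39.7% were 24 nt long in cotyledon, against 35.7% in root, 33.8% in stem and 35.4% in leaf. Each distinct 24 nt sequence was read 1.69 times on average in cotyledon, 1.73 times in root, 2.12 times in stem and 2.07 times in leaf. With every library thinned at random to the 8044543 reads of root, cotyledon held 1039023 distinct 24 nt sequences, root 657070, stem 508673 and leaf 549017. The shorter classes were more diverse in cotyledon as well. At that depth it held 414527 distinct 21 nt sequences, 1.68 times the 246345 of stem, which was the next highest, and 345509 distinct 22 nt sequences, 1.60 times the number in stem. The 24 nt ratio to the next highest library was 1.58. When each distinct sequence was counted once, the ratio of 24 nt to 21 nt sequences was no longer highest in cotyledon: it was 2.53 there, 2.90 in root, 2.10 in stem and 2.71 in leaf.

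**Figure D2:**
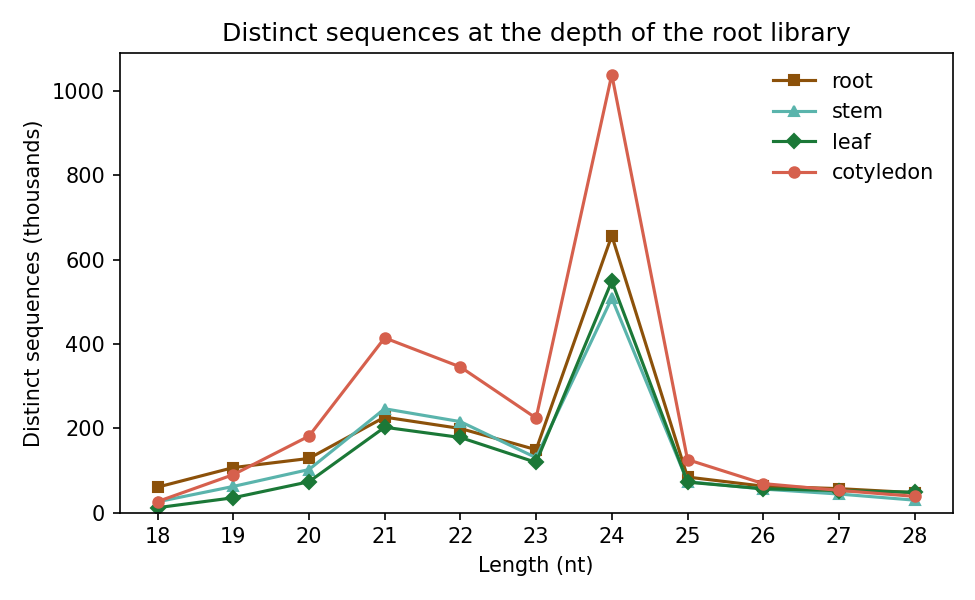
Number of distinct sequences (axis in units of 1000) at each length from 18 to 28 nt, after every library was thinned to the depth of the root library, with 1 line per library. Cotyledon lies above the other libraries from 20 to 26 nt, at 1.58 times the next highest at 24 nt and 1.68 times at 21 nt.

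The first base also set the cotyledon 24 nt reads apart. An adenine at the 5' end, the base favoured by the Argonaute proteins of the DNA methylation pathway, opened 45.3% of 24 nt reads in cotyledon (95% Wilson interval 45.27 to 45.39). It opened 36.9% in root, 32.1% in stem and 32.6% in leaf. With listed rRNA and tRNA pieces left out the shares were 45.6% in cotyledon, 36.7% in root, 32.03% in stem and 37.5% in leaf, so these pieces lowered the leaf share. Over distinct 24 nt sequences the shares were closer, at 48.9% in cotyledon, 46.1% in root, 36.8% in stem and 42.2% in leaf. Uracil, the usual first base of miRNAs, opened 47.7% of 21 nt reads in cotyledon, 59.8% in stem and 57.3% in leaf. Root had the lowest share of 21 nt reads that began with uracil, 38.4%, and 29.1% of its 21 nt reads began with cytosine.

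Most conserved miRNA families took a smaller part of the cotyledon library. Among 35 families listed in advance, 28 had at least 100 reads in a library, and 23 of these were below the mean of the other 3 organs in cotyledon in RPM (reads scaled to a library total of 1000000). At least 4-fold lower in cotyledon were 14 families against root, 9 against stem and 11 against leaf, while 1, 2 and 3 families were at least 4-fold higher. The listed sequences made up 3.14% of cotyledon reads, 4.25% of root, 10.9% of stem and 6.69% of leaf reads. The median over the 28 families was -2.18 on the log2 scale for cotyledon against the mean of the others, at percentile 0.1 of 10000 random lists of other 20 to 22 nt sequences of like level, whose median was -0.28.

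These counts depend on what the libraries are scaled to. TMM factors, which assume that most listed families are equal, raised cotyledon by 2.45, 1.91 and 2.14 on the log2 scale against root, stem and leaf and brought the median to -0.05. The split of families at least 4-fold higher and lower then became 10 and 7 against root, 4 and 5 against stem, and 6 and 3 against leaf. With median-of-ratios factors over the listed families it was 9 and 7, 4 and 6, and 6 and 3. With such factors over the other 20 to 22 nt sequences it was 1 and 15, 3 and 6, and 1 and 14. Of the 84 comparisons of a family with an organ, TMM turned 27 round. Of the 28 families, 11 kept their direction against all 3 organs under every scaling: miR157, miR164, miR167, miR168, miR169, miR395, miR396, miR1510, miR1511, miR2119 and miR3522. Of these 11, all but miR157, miR167 and miR1510 also kept it when length variants or sequences with 1 changed base were added.

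Counted by their listed sequences, miR157, miR164, miR168, miR169 and miR396 were at least 4-fold below all 3 other organs in cotyledon, with at least 100 reads in each of those organs. Without that minimum, miR395, miR399 and miR2119 were at least 4-fold below all 3 as well. In cotyledon miR395 and miR399 had 1 read each and miR2119 had 0. The miR157 sequence, a close relative of miR156, which targets SPL transcription factors that set the timing of developmental phases, had 5.84 RPM in cotyledon. Its lowest level elsewhere, 379 RPM in stem, was 64.9-fold higher (95% exact interval 51.9 to 82.3). miR396, which targets the GRF growth regulators, had 131 RPM in cotyledon and 4333 RPM in leaf, a 33.1-fold difference (31.5 to 34.7). Both miR396 sequences took part, with miR396a at 18.3 RPM in cotyledon against 6287 in stem and miR396b at 113 RPM against 3162 in root. miR169, which targets NF-YA transcription factors, was 13.2-fold below root (9.82 to 17.98). miR164, which targets NAC transcription factors that draw organ boundaries, was 6.37-fold below root (5.70 to 7.13). miR168, which targets the Argonaute gene AGO1, was 5.08-fold below leaf (4.89 to 5.28). Under TMM and under median-of-ratios factors over the listed families, miR157 and miR396 stayed past 4-fold below all 3 organs. Under both, miR164, miR168 and miR169 did not, and miR168 fell short also under the factors over other 20 to 22 nt sequences. When sequences with 1 changed base were added, miR157 turned round and was 1.92 times as high in cotyledon as in the highest other organ.

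No listed family was at least 4-fold above all 3 other organs in cotyledon, although 4 were above each of them under every scaling. miR1510, which targets disease resistance genes, had 209 RPM in cotyledon, 3.74 times root, 6.83 times stem and 6.12 times leaf. With sequences that start or end up to 2 nt away added, its cotyledon level was 0.681 times root, 2.95 times stem and 2.09 times leaf, so the direction against root turned and both 4-fold calls ended. miR1511 had 160 RPM, 5.35 times root, 2.85 times stem and 5.66 times leaf, which became 1.92, 3.68 and 2.77 times with length variants, short of 4-fold throughout. miR3522 had 334 RPM, 1.97 times root, 77.3 times stem and 10.5 times leaf. miR167, which targets the auxin response factors ARF6 and ARF8, had 192 RPM, 1.30 times root, 3.07 times stem and 3.71 times leaf, but 0.813 times leaf once sequences with 1 changed base were added. Both scalings over the listed families put these 4 past 4-fold above all 3 organs for the listed sequences.

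**Figure D3:**
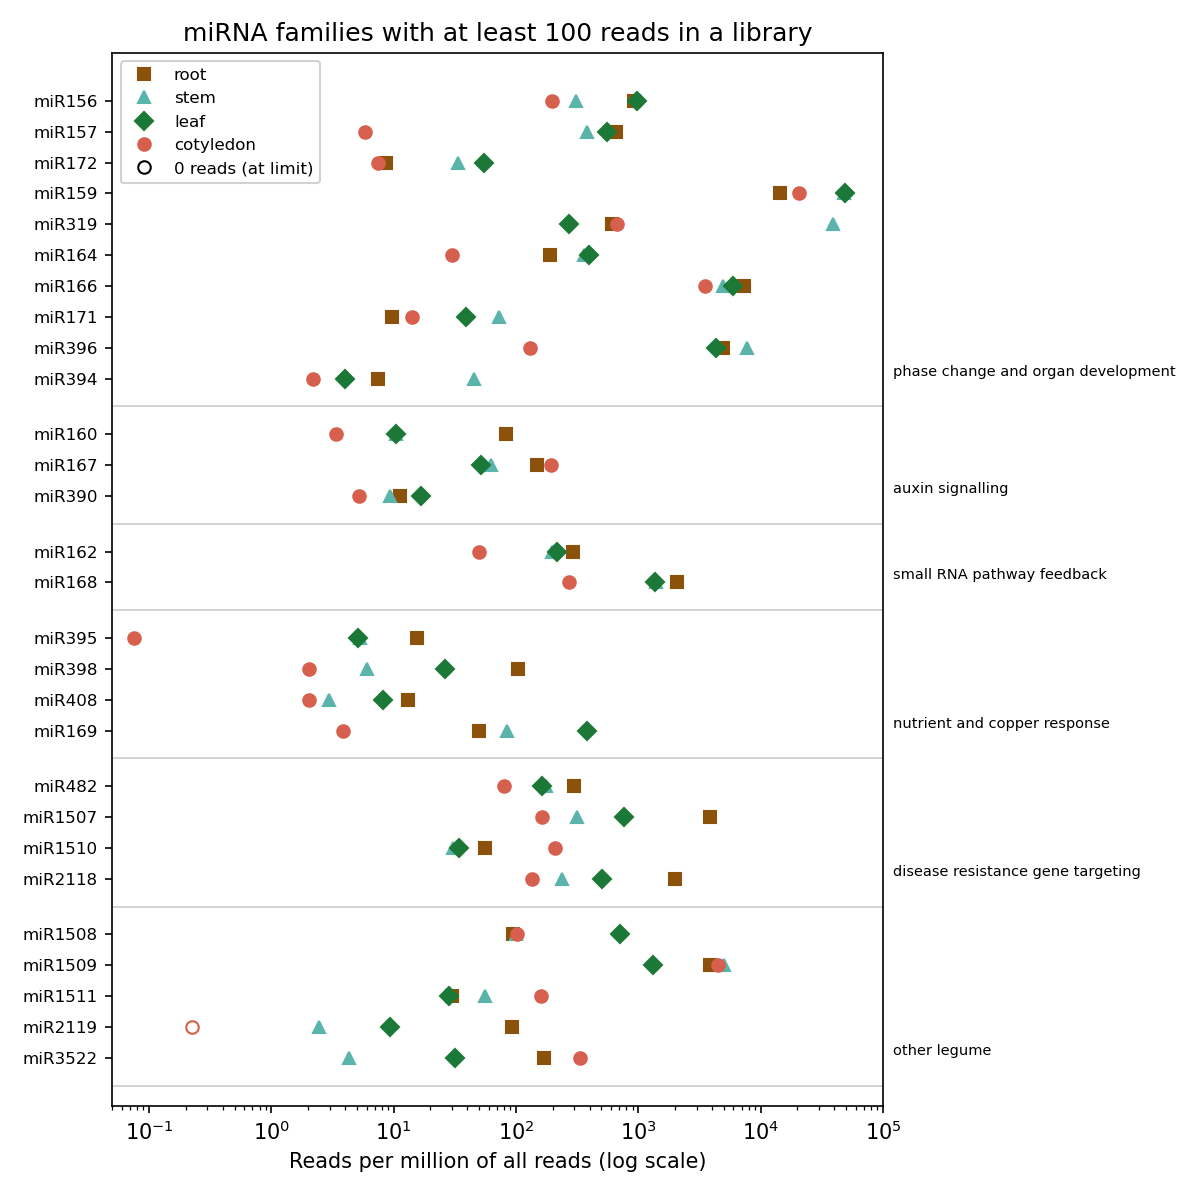
RPM, scaled to all reads (log axis), for each miRNA family with at least 100 reads in a library, grouped by list, with 1 point per library and an open point at the limit that 0 reads allow. Cotyledon points lie furthest left for miR157, miR164, miR168, miR169, miR395, miR396 and miR2119 and furthest right for miR167, miR1510, miR1511 and miR3522. No scaling turned this order round, although adding other forms turned it for miR157, miR167 (leaf) and miR1510 (root).

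The families were grouped into 6 lists. In the list of phase change and organ development, all 10 members were measured, all 10 were below the mean of the other organs in cotyledon, and 3 of them were at least 4-fold below each organ. The median was -2.62 on the log2 scale, at percentile 2.17 of random lists, and became -1.84 with 1 base change added, which turned miR157, one of the 3, above every organ. Being below the mean does not mean below each organ. Cotyledon miR319 was 1.09 times root and 2.47 times leaf, and miR159 and miR171 were 1.42 and 1.45 times root. miR159, which targets GAMYB transcription factors, was the most abundant family in every library, at 14510 RPM in root, 47770 in stem, 48653 in leaf and 20562 in cotyledon, and TMM turned its cotyledon value from below to above stem and leaf. miR166, which targets HD-ZIP III transcription factors, had 7355 RPM in root, 4948 in stem, 5988 in leaf and 3524 in cotyledon, and TMM put cotyledon above all 3. miR156 had 920 RPM in root, 312 in stem, 984 in leaf and 196 in cotyledon, with cotyledon above root and stem under TMM. With 1 base change added it had 982, 336, 1062 and 307 RPM in the same order, and miR157 had 723, 419, 612 and 1387 RPM. The main cotyledon read in that miR157 count is, without its first base, a version of miR156. The split of reads between these close relatives is thus uncertain. They were not counted as a joint family, so a joint deficit in cotyledon was not shown. miR172, which targets AP2 transcription factors, had 8.70, 33.6, 54.8 and 7.48 RPM in the same order, and cotyledon was above root under TMM. The list of nutrient and copper response stood furthest from random lists. It had 4 of its 6 members measured, all below the mean, with a median of -4.99 at percentile 0.09. Of the members not measured, miR397 went the other way once length variants were added. It then had 37.9 RPM in cotyledon, 25.2 in root, 1.75 in stem and 0.248 in leaf. miR399 stayed low in cotyledon, with 1 read there and 19 in root. miR395, which acts in sulfate supply, had 1 read in cotyledon and 124 in root, a ratio of 206 in RPM (36.3 to 8202). With length variants it had 50 reads in cotyledon and 271 in root, and cotyledon was at 0.111 times root. miR398, which targets copper superoxide dismutase, had 103 RPM in root, 6.07 in stem, 26.2 in leaf and 2.02 in cotyledon, where TMM raised cotyledon above stem. Under TMM the medians of these lists were -0.58 and -2.75, and under median-of-ratios factors over the listed families -1.04 and -3.21.

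Smaller or no departures from random lists were seen in the remaining groups, with medians that TMM moved to 0.91 for auxin signalling, -0.22 for small RNA pathway feedback, 0.19 for disease resistance and 2.53 for the other legume families. The auxin signalling list had 3 of 5 members measured, with a median of -1.25 at percentile 22.6. Its member miR393 was not measured as listed. With length variants it had 40.6 RPM in root, 73.1 in stem, 96.9 in leaf and 4.64 in cotyledon, at least 4-fold below all 3 organs. In the same list miR160, which targets the repressors ARF10, ARF16 and ARF17, had 82.2 RPM in root, 10.4 in stem, 10.4 in leaf and 3.37 in cotyledon, which TMM placed above stem and leaf. The list of small RNA pathway feedback had 2 of 3 members measured, with a median of -2.41 at percentile 23.99. In it miR162, which targets the Dicer gene DCL1, had 49.5 RPM in cotyledon and was 5.86-fold higher in root, 3.96-fold in stem and 4.38-fold in leaf, a direction TMM turned against leaf. No read matched the listed miR403 sequence, which allows up to 0.224 RPM in cotyledon and 0.373 RPM in root. The list targeting disease resistance genes had 4 of 5 members measured, with a median of -2.08 at percentile 16.6. There miR1507 had 3885 RPM in root, 316 in stem, 763 in leaf and 163 in cotyledon, which TMM and median-of-ratios factors over the listed families placed above stem. miR2118 had 1978, 236, 501 and 135 RPM in the same order, and both factors placed cotyledon above stem, as TMM did above leaf. The median of 5 measured legume families outside these groups was 0.40, at percentile 76.1. Among them miR1509 was the second family of cotyledon by listed sequences, at 4522 RPM, close to 3874 in root and 5047 in stem and above 1327 in leaf. With length variants miR1511 was above it in cotyledon, at 5165 against 4920 RPM. The order of miR1509 against root and stem turned under the factors over other 20 to 22 nt sequences, as it did against stem under TMM and with 1 base change added.

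Root, stem and leaf each had families of their own, which the comparison of these organs with each other was meant to show. In root, miR160 was 7.88-fold above the next organ (95% exact interval 6.27 to 10.0), miR1507 5.09-fold (4.95 to 5.23) and miR2119 9.97-fold (7.85 to 12.8). miR2119 had 746 reads in root and none in cotyledon, where it was 413-fold lower at the limit of 3 reads, with a lower end of the exact interval of 335. In stem, miR319, which targets TCP transcription factors that control leaf growth, had 39178 RPM and was 58.5-fold above the next organ (57.2 to 59.7). This excess was 15.6-fold under TMM, 21.6-fold under median-of-ratios factors over the listed families and 39.1-fold under those over other 20 to 22 nt sequences. miR394, which targets an F-box gene of the shoot meristem, was 6.06-fold above (4.62 to 8.07), and miR3522 was 7.35-fold below leaf, the nearest organ (5.29 to 10.4). In leaf, miR169 was 4.51-fold above the next organ (4.18 to 4.88) and miR1508 6.98-fold (6.57 to 7.41). Root exceeded stem by at least 4-fold in 7 families and was exceeded in 3, counts that became 6 and 5 under TMM and 9 and 2 under the factors over other 20 to 22 nt sequences. Root against leaf had 4 and 4, which became 2 and 5 under the latter factors. Stem against leaf had 2 and 4, which became 3 and 2 under TMM and 2 and 7 under the latter factors. None of these 8 differences changed direction under any scaling, but the 2 leaf families fell short of 4-fold under TMM (3.85-fold for miR169, 1.58-fold for miR1508), as did miR1507 and miR394 under the factors over other 20 to 22 nt sequences. With length variants added, the leaf excess of miR169 was 2.46-fold.

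Over all sequences, the listed miRNAs included, 18489 had at least 100 reads in a library. Of these, 594 were at least 4-fold above all 3 other organs in cotyledon and 79 at least 4-fold below. A call above needs 100 reads in the 1 organ, but a call below needs them in each of the other 3. Counts above and below are therefore not on equal terms. The counts above and below were 2211 and 314 for root, 362 and 10 for stem, and 1756 and 147 for leaf. No genome was used here, so these sequences, abundant ones in root among them, were not assigned to an organism. The share that stood above the other organs in cotyledon was highest at 22 nt, with 168 sequences (6.63%), against 130 at 21 nt (4.12%) and 54 at 24 nt (3.26%). This peak was not particular to cotyledon. In stem the share was highest at 22 nt as well, with 164 of 2534 sequences, against 95 of 3155 at 21 nt and 6 of 1658 at 24 nt. Among sequences outside the miRNA list with at least 1000 reads, the largest cotyledon excess was found for the 21 nt sequence GCTCTCTCTTCCTCTGTCATC. It had 5088 reads in cotyledon, 2 in stem, 2 in leaf and none in root. This was 1021-fold above the limit that root allows, with a lower end of the 95% exact interval of 830. The 22 nt sequence TTGGTTGTTCCTGGTAGGTGTC had 9336 reads in cotyledon and 9 in leaf, a 626-fold difference (329 to 1369). Neither came within 2 base changes of a listed miRNA over at least 18 aligned bases. The other 3 were versions of miR157 and miR156. TTGACAGAAGAGAGAGAGCAC had 18435 reads in cotyledon and 30 in leaf, 371-fold more (260 to 549), and differs from miR157 by T12G, counted from 1 at the 5' end of the listed miRNA. Set without gaps against GCTCTCTCTTCCTCTGTCATC as an opposite strand with a 2 nt overhang, it paired at 13 of 19 positions. It paired at 13 of 20 with a 1 nt overhang and at 8 of 18 with 3 nt. Pairing with a bulge was not counted, which such counts would miss, and no chance value was computed, so a link between them stays open. Its form without the last base, TTGACAGAAGAGAGAGAGCA, had 1428 reads in cotyledon and 3 in leaf, and its form without the first base, TGACAGAAGAGAGAGAGCAC, had 1298 in cotyledon and 3 in stem. This last form differs from miR156 by T14A.

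Of the 5 sequences outside the miRNA list with the largest deficit in cotyledon, 3 were related to miR396. TTCAATAAAGCTGTGGGAAG, which pairs with miR396a as its opposite strand, had 42 reads in cotyledon and was 93.5-fold higher in root (69.0 to 130). Its longer form GTTCAATAAAGCTGTGGGAAG was 25.7-fold higher in root (23.5 to 28.2). TTCCATAGCTTTCTTGAACTG, a version of miR396a with the change C6T, had 5 reads in cotyledon and was 62.8-fold higher in root (26.4 to 196). TCGGACCAGGCTTCATTCCCT, a version of miR166a with the change C21T, was 27.0-fold higher in stem (22.2 to 33.3). TATGGGATAAATGTGAGCTCA, which resembles no listed miRNA, was 28.3-fold higher in leaf (16.2 to 54.0). No scaling turned any of these 10 sequences round.

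Fragments of ribosomal and transfer RNA differed between the organs as well. Listed pieces of these RNAs made up 8.83% of reads in root, 10.7% in stem, 21.1% in leaf and 13.1% in cotyledon. Plastid ribosomal pieces were most frequent in leaf, with 13.2% of reads there, 2.39% of stem, 1.38% of cotyledon and 0.0970% of root reads, and a plastid tRNA-Asp piece had 2.26% in leaf. Pieces of 5.8S rRNA were most frequent in cotyledon, at 8.03%, against 2.43% in root, 4.61% in stem and 3.08% in leaf. The 5' end of 18S rRNA was most frequent in root, at 5.32%, against 2.27% in stem, 1.995% in leaf and 2.89% in cotyledon. Reads of 18 and 19 nt made up 13.8% of the root library, 6.68% of stem, 3.32% of leaf and 6.39% of cotyledon. With all listed pieces left out, 24 nt reads were 22.1% in cotyledon, 15.1% in root, 13.5% in stem and 14.98% in leaf.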

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

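Both tests in this part were chosen as tests of an explanation after the result was seen. Reads of 28 to 36 nt lie beyond the gel range given in the labels and are not a size class of any planned result, and they stood out because their share exceeded what 0 reads allow. They were 5.30% of reads in root, 3.12% in stem, 15.8% in leaf and 4.30% in cotyledon. Those of 36 nt alone were 0.147% in root, 0.0645% in stem, 0.705% in leaf and 0.0895% in cotyledon.

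The 24 nt share of cotyledon reads was 20.2%, 1.43 times the highest other organ. If fragments of longer RNAs filled the 24 nt class, the excess should shrink once the mean of 23 and 25 nt reads is subtracted. In percentage points over the highest other organ it stayed, at 6.06 before and 6.05 after. The ratio rose to 1.93 because the shares compared became smaller. Fragments that gather at 24 nt itself were not tested. If a few abundant sequences made it, leaving out the 10 most abundant of each library should end it. The ratio was then 1.43 to stem, which became the highest other organ in place of leaf, and 1.47 to leaf. These 10 were taken over all lengths, so this does not test abundant 24 nt sequences as such. A difference in organ, in stage or perhaps in place of growth may lie behind it, and the design leaves these open and untested, as it does a difference between single libraries.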

How the results depend on the processing

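Shares of 24 nt reads are given as root, stem, leaf and cotyledon, and the cotyledon share was above the other 3 in every setting tried. They were 14.5, 13.2, 16.02 and 20.6% among reads of 18 to 28 nt (cotyledon over the highest other 1.28), and 35.7, 33.8, 35.4 and 39.7% with each distinct sequence counted once (1.11). Without the 10 most abundant sequences they were 15.03, 15.2, 14.7 and 21.7%, and among sequences seen at least 2 times 8.21, 9.18, 9.56 and 13.7% (1.43). Chosen after seeing the data, leaving out listed rRNA and tRNA pieces gave 15.1, 13.5, 14.98 and 22.1% (1.47), and 24 nt reads above the mean of 23 and 25 nt gave 6.505, 5.82, 6.002 and 12.6% (1.93). The ratio of 24 to 21 nt reads became 0.418, 0.335, 0.448 and 0.581 with 22 nt reads added to the denominator. It became 0.882, 0.708, 0.873 and 1.18 without the 10 most abundant sequences. Over distinct sequences it was 2.90, 2.10, 2.71 and 2.53, so that cotyledon then fell below root and leaf. The 24 nt share of distinct sequences was 33.4% in stem and 39.3% in cotyledon after thinning, and 20.98, 24.6, 19.9 and 37.1% among sequences seen at least 2 times. After thinning, reads per distinct sequence at 21 nt were 8.11 in stem and 4.08 in cotyledon, and at 24 nt 2.06 and 1.57.

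Among counts of families past 4-fold, TMM placed cotyledon higher than root in 10, stem in 4 and leaf in 6 families and lower in 7, 5 and 3. It gave 5 families with root below stem and 2 with stem below leaf. Median-of-ratios factors over the listed families gave 9, 4 and 6 families higher in cotyledon, 7 lower than root and 3 lower than leaf, 5 with root below stem and 2 with stem below leaf. Such factors centre the listed families, so the change follows from their construction. A 2-fold threshold gave 2, 4 and 6 families higher in cotyledon than root, stem and leaf, and 16, 13 and 16 lower. It gave 5 with root below stem, 10 with root above leaf and 7 with stem below leaf. Without a minimum of reads 5 families were higher in cotyledon than leaf, and with length variants 2 were lower in stem than leaf. Median-of-ratios factors over other 20 to 22 nt sequences, added after seeing the data, gave 1 family higher in cotyledon than leaf, 2 higher in root than leaf and 7 lower in stem than leaf. The cause was not tested except where named.

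Results that turned round included the miR157 deficit, which became 0.302 (lowest other organ over cotyledon) with 1 base change allowed because of TTGACAGAAGAGAGAGAGCAC. Also turned were miR1510 against root, at 0.681 (cotyledon over root) with length variants, and miR167 against leaf, at 0.813 with 1 base change. The auxin signalling median became 0.91 under TMM and 0.46 under median-of-ratios factors, and the median of the list targeting disease resistance genes became 0.19 under TMM. Of the other values, named families against the nearest organ stayed within their intervals in 36 of their recomputed values and moved without turning in 54, upward in 12 and downward in 42. The ratios of the 4 families above all 3 organs stayed in 30 and moved in 52 (35 up, 17 down). Named sequences stayed in 33 and moved in 17 (5 up, 12 down), list medians stayed in 10 and moved in 23 (16 up, 7 down), and shares of 24 nt reads starting with A stayed in 1 and moved in 7 (6 up, 1 down). No paired analysis was possible because each organ has 1 library and no test was made. Settings for genome windows, for chromosomes alone, for density around genes and for gene lists were not run, since no genome or positions were used here. As listed, 7 of the 35 families had under 100 reads in every library, but depth is not the limit for all of them. With length variants miR2109 had 15541 reads in root, where the listed form had 9, and miR1514 had 1815 in cotyledon, where it had 30. Likewise miR397 had 506 in cotyledon, where the listed form had 12, and miR393 had 781 in leaf, where it had 7.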

Other observations

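Members of 1 family did not always share an organ pattern. In cotyledon miR172a had 3 reads and miR172b 97, while in leaf they had 432 and 10, so the family total hides a change of its main sequence. miR396a exceeded miR396b in stem, at 6287 against 1439 RPM, and lay below it in root, at 1809 against 3162 RPM, and in cotyledon, at 18.3 against 113 RPM. miR398a had 85.0 RPM in root against 18.02 for miR398b, and in cotyledon 1 read against 26. miR2119 followed the order of miR398a over the 4 organs, with 92.7 RPM in root, 2.47 in stem, 9.31 in leaf and 0 reads in cotyledon, against 85.0, 2.37 and 15.4 RPM and 1 read.

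Versions 1 base away from a listed miRNA carried much of some families. TGAAGCTGCCAGCATGATCTT, miR167a with A21T, had 629 RPM in cotyledon, 177 in leaf, 145 in root and 12.04 in stem, and so exceeded the listed miR167 sequence in cotyledon and leaf. TGAAGCTGCCAGCATGATCTG, miR167a with A21G, had its highest level in leaf, at 876 RPM against 66.1 in root, 2.78 in stem and 62.6 in cotyledon. TTAATCAAGGAAATCACGGTTG, miR1509a with C21T, had 2049 RPM in cotyledon and 386 in leaf. TCGGACCAGGCTTCATTCCCG, miR166a with C21G, ran from 1208 RPM in root and 836 in stem to 373 in leaf and 27.7 in cotyledon. For the miR403 family and the TAS3 trans-acting siRNA, whose listed sequences had at most 8 reads in a library, versions with C20T were present, with 5.76 RPM of TTAGATTCACGCACAAACTTG and 38.5 RPM of TTCTTGACCTTGTAAGACCTC in cotyledon.

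At equal depth 14.98% of distinct 24 nt sequences of cotyledon and 15.4% of those of 21 nt were found in another library, against 17.7 and 25.3% in root, 26.1 and 31.9% in stem and 24.2 and 35.3% in leaf. Cotyledon held more distinct sequences of both lengths. The numbers shared at 24 nt were highest in cotyledon, at 155682, against 116140 in root, 132816 in stem and 132699 in leaf. At 21 nt they were 63788, 57262, 78679 and 71449 in the same order.

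The tests in the next paragraphs were chosen after the results were seen, apart from those of sequencing errors and of dilution by any other reads. Cotyledon held more distinct 21 and 22 nt sequences than any other organ at equal depth, 1.68 and 1.60 times the next highest. If fragments of longer RNAs were the cause, lengths outside the Dicer range should show the excess too. Among 18, 19, 26, 27 and 28 nt the highest ratio of cotyledon was 1.10 to root, 1.45 to stem and 2.56 to leaf. Such fragments cannot be told apart from other sources for stem and leaf. For root they are argued against at these lengths only. At 20, 23 and 25 nt the ratio to the next highest, which was root, was 1.41, 1.502 and 1.49, so the excess is wider than the 21, 22 and 24 nt classes. These values lie above 1.37, the midpoint used to decide for root. The reading for root thus depends on leaving these lengths out, and fragments stay open there too. Leaving out sequences 1 base from an abundant 21 nt sequence gave a ratio of 1.69, but this removed 0.632% of cotyledon sequences, too few to decide on sequencing errors. A wider set of small RNA loci in cotyledon is another candidate explanation that no genome was at hand to test, and organ, stage and place of growth stay open as well.

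The listed miRNA families lay lower in cotyledon, with a median of -2.18 on the log2 scale. If reads outside 20 to 22 nt had diluted them, the median scaled to 20 to 22 nt reads alone should be near 0, but it was -2.22. If other reads of any length had diluted them, other 20 to 22 nt sequences with at least 100 reads in root, stem or leaf should be as low, but the median of these 6312 was -0.64. If cotyledon used versions of the listed length with 1 changed base in most families, allowing that change should bring the median near 0, but it was -2.03. With length variants it was -2.07. Versions that differ in both ways or by more bases were not counted, and a median can stay low while single families switch. Versions that the list lacks thus stay open as a cause. For miR157, cotyledon was 1.92 times the highest other organ with 1 base change allowed, and 18435 of its 18537 reads were TTGACAGAAGAGAGAGAGCAC. That sequence had been seen before this count was made, so whether it takes the place of the listed miR157 sequence in cotyledon was not tested. Amounts per cell stay open, since no added standard gives an absolute scale.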
